A study of Mus musculus with 8 samples.

How the data were processed

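Whole encapsulated cochleae were taken from mice at postnatal day 16, and both cochleae of an animal were pooled as 1 biological replicate, per the labels' protocols. Total RNA that included small RNA was purified, converted with the WT PLUS kit and hybridised to Affymetrix Mouse Gene 2.0 ST arrays. The 8 arrays comprised 4 miR-183/96 knockout animals and 4 control animals. The values are log2 expression values, made by the authors with RMA at gene level in Affymetrix Expression Console, per the labels and the submitters' processing notes. RMA consists of background correction, quantile normalization and a median-polish summary of the probes of each feature. The software version, the annotation release and the set of arrays normalized together are not given in the sources used here. The log2 scale was read from the values, which ran from 0.90 to 13.5, with medians between 5.10 and 5.28. No background level or detection call was used here, so dim features could not be separated from background, and the number of arrays limits the precision. No scan date or batch was used here.

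The value table held 41345 features. The platform annotation linked 23521 features to exactly 1 gene symbol, 1814 to several and 16010 to none, and the features of 1 symbol, covering 22180 genes, were tested. Of these, 23328 had an identifier in the RefSeq gene table of assembly GRCm38.p6, with 0 symbols differing. The array's own genome build is not given in the sources used here, so that table served only for names and for which genes lie near each other, and no coordinates are printed. Where a gene had several features, the feature with the highest mean over the 8 arrays stood for it.

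Knockout was compared with control in limma 3.58.1 under R 4.3.3, by lmFit and eBayes with an intensity trend and with genotype as the only term. The p-values were adjusted by the Benjamini-Hochberg method over all tested features, with a threshold of 0.05 and no fold threshold. All log2 differences are knockout minus control, with limma's standard error (SE). Single measures per animal were compared with two-sided exact permutation tests over the 70 assignments of 8 arrays to groups of 4, whose smallest p is 0.0286.

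Gene lists were fixed before the data were examined, as were the groups, the main test, the naming rule and the alternatives not listed below as later choices. There were 26 lists with 416 symbols, of which 372 were measured; the remaining symbols were not analysed here. Each list was tested with camera at its preset correlation of 0.01, with adjustment over the 26 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Each list median was also placed among those of 10000 random lists matched on mean level, as the percentile of random medians at or below it, a comparison chosen after seeing the data. The random lists draw genes independently, so a percentile is not a p-value and ignores correlation among genes and spread between animals. The naming rule took all genes past the adjusted threshold when at most 30 passed, the 3 genes of the targeted cluster, and up to 4 members of each list with the smallest p. Because fewer than 10 genes passed, the 8 highest and the 8 lowest log2 differences at an unadjusted p under 0.01 with no overlap between groups were named too, as not having passed.

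The steps were tested on simulated data with the means and the eBayes-moderated spreads of the 23521 features. In the knockout against control design, 100% of 50 features changed by 1.5 on the log2 scale were called, 98% of 50 changed by 1, 60% of 50 changed by 0.6 and 2% of 50 changed by 0.3. There were 12 false calls in that simulation, and 0 calls in 1 without any change. In a separate simulation camera called a list shifted by -0.3 and 0 other lists. The simulated features varied independently of each other, so this does not show how often camera calls unchanged lists whose genes vary together. Nor does it show how often unchanged features are called where whole arrays differ, as in signal range.

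The alternatives were the replicate number as a block, eBayes without the trend or with robust variance, all features of the table, features with a mean of at least 5 or in the upper part by mean, median-centring, repeated quantile normalization, array weights, and covariates for Y-linked, blood and marrow, and muscle levels. Leaving out each array in turn, other thresholds, the other list tests and other distances from the locus were also run. Chosen after seeing the data were cyclic loess normalization, the signal range of each array (the SD of its log2 values) as a covariate, the removal of both arrays with extreme muscle levels, the hair cell lists without Calb2, the hair cell list without the muscle-expressed genes Pvalb, Xirp2, Smpx, Lmod3 and Rbm24 and again without Calb2, Pcp4 and Myo6 too, and the locus comparison without Mir183, Mir96 and Mir182. The planned grouping of genes by microRNA seed matches was not run, since no 3 prime UTR sequences were used here. Figures were drawn with matplotlib.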

Results

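Gene expression was measured in the cochlea of 4 knockout mice that lack the microRNA genes Mir183 and Mir96 and of 4 control mice, all at postnatal day 16. These microRNAs belong to a cluster, with Mir182, that is expressed in sensory cells. Each array represents 1 animal. The arrays correlated with each other at 0.947 to 0.976 over all features of the value table. The comparison addressed which cochlear transcripts differ when the cluster is targeted.

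The targeted locus was examined first. Mir96 fell by 1.48 on the log2 scale (SE 0.17), from 5.69 ± 0.40 in control to 4.21 ± 0.13 in knockout cochlea (SD, n = 4; limma adjusted p = 0.00932). Its feature read 4.01 to 4.31 in the 4 knockout animals and 5.26 to 6.23 in the 4 control animals, so no array went against its label. The call was lost without control replicate 1 (adjusted p = 0.0677). Mir183 differed by -0.33 (adjusted p = 0.398), at a mean level of 2.41 that lay at the 3.5th percentile of all features, too dim to check the labels. Mir182, which the labels do not name as deleted, differed by 0.35 (adjusted p = 0.364). Its mean level of 3.75 was also dim, at the 12.6th percentile. The difference was 0.21 after cyclic loess and 0.0071 with signal range as a covariate, so it does not show whether Mir182 changed. Whether these features lie inside the deleted segment was not analysed here.

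Calb2, Mir96 and Snap25 fell in knockout cochlea, and 0 features rose, out of 23521 tested. Calb2, the calcium-binding protein calretinin of inner hair cells and a subset of auditory neurons, fell by 1.60 (SE 0.14), which is 3.03-fold lower, from 7.55 ± 0.20 to 5.96 ± 0.26 (SD, n = 4; adjusted p = 0.000753). Snap25, a presynaptic membrane fusion protein, fell by 1.09 (SE 0.15), from 8.27 ± 0.19 to 7.18 ± 0.31 (SD, n = 4; adjusted p = 0.0389). Their features were 17512872 for Calb2, 17465480 for Mir96 and 17376822 for Snap25. In each of the 3 genes all 4 knockout values lay below all 4 control values. Snap25 kept its call in 6 of 23 alternatives, not in cyclic loess (-0.87, adjusted p = 0.219), and Calb2 in 22 of 23, not with signal range as a covariate (-1.48, adjusted p = 0.0506). Without control replicate 3 the count of called features was 21, with 16 higher, and without control replicate 1 it was 1.

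**Figure D1:**
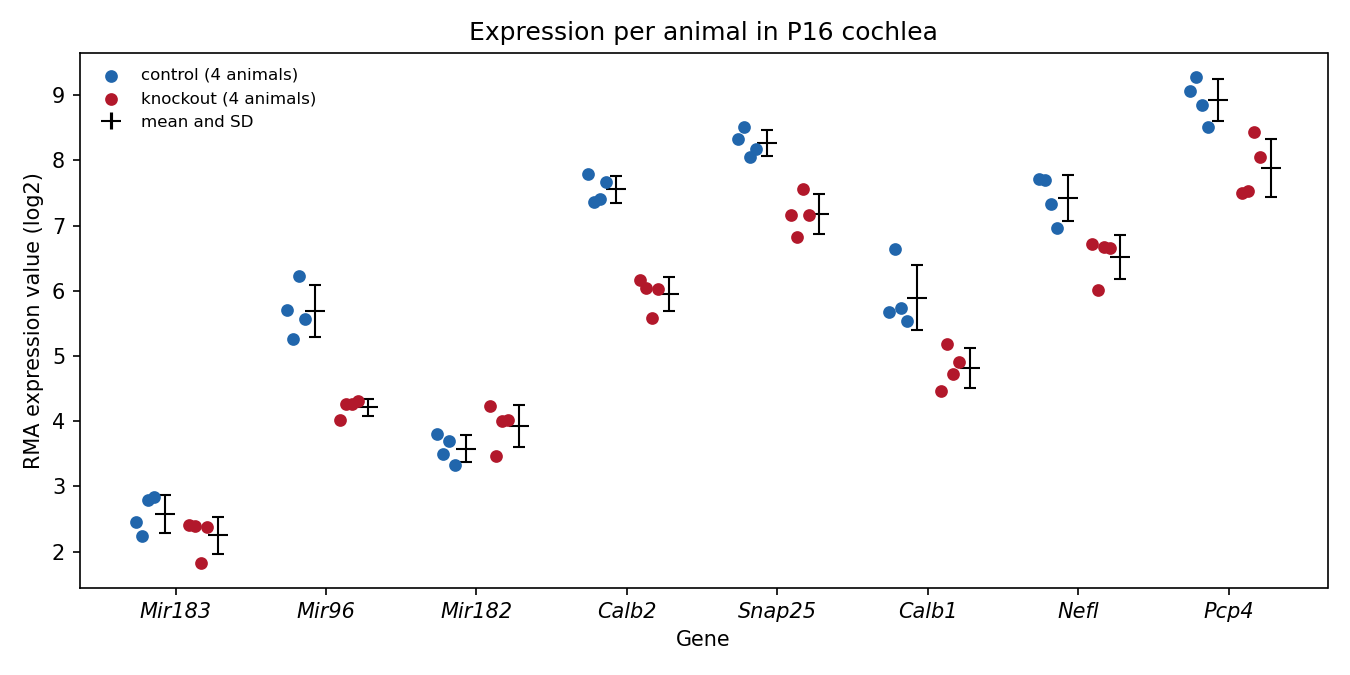
RMA expression values (log2, vertical axis) of 8 genes (horizontal axis) in 4 control (blue) and 4 knockout (red) animals, with each point 1 animal and the black marks the mean and SD. Calb2 sits at 5.96 ± 0.26 in knockout and 7.55 ± 0.20 in control animals, and Mir183 and Mir182 overlap between the groups.

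Features that did not pass were named at each end. Among the lowest, Calb1 (calbindin) was at -1.08, Pcp4 at -1.04, Fgf12 at -0.93, the neurofilament genes Nefl at -0.91 and Nefm at -0.73, Clec2l at -0.84, Vsnl1 at -0.81 and Tpm2 at -0.77. Among the highest, the olfactory receptor gene Olfr99 was at 1.33 (adjusted p = 0.0511), Zfp600 and Zfp972, 2 zinc finger genes, were each at 1.08, Khdc1a was at 0.97, Gm906 at 0.95, Vmn1r208 and Gm2022 at 0.92 and Gm14327 at 0.90. A second feature of Vmn1r208 read 0.19. At an unadjusted p under 0.05 there were 3361 features, 1655 higher and 1706 lower, against 1176 expected without effect. That count was 1902 without control replicate 4, 2023 without control replicate 2, 2116 without knockout replicate 4 and 5501 without control replicate 3. It was 1308 with the Y-linked and 1400 with the signal range covariate, and 4 splits that mixed the groups gave more, 3440 to 6950. At that p, 207 differed by at least 1.5-fold, 155 higher and 52 lower, and the count was 379 without knockout replicate 2 and 488 without control replicate 3. With signal range as a covariate it was 297, with 148 higher and 149 lower. Groups did not overlap at 1401 features, 5.96% of those tested, where chance gives 2.86%.

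Neuronal genes formed a group with several lower members. In the spiral ganglion neuron list, 1 of 26 measured members fell over all features and 6 fell when adjusted over the list alone: Snap25, Calb1, Nefl, Nefm, Nefh (-0.52) and the potassium channel gene Kcna1 (-0.34). Other members were close to 0, such as Syt1 at -0.03 and Isl1 at -0.01. The list median was -0.10 (camera adjusted p = 0.00221), and the call was lost with an estimated correlation (adjusted p = 0.539). The mean level of the list was 5.50 ± 0.10 in knockout and 5.71 ± 0.11 in control animals (SD, n = 4; exact permutation p = 0.0571). In the Schwann cell and myelin list, Mal (-0.57) and Ugt8a (-0.44), both of myelin, fell when adjusted over the list alone among 13 members. Mag was at -0.35 and Ncmap at 0.28. After cyclic loess Mal read -0.44 and Ugt8a -0.24. Ugt8a then missed the 0.05 threshold even before adjustment, and the adjustment over the list alone was not repeated. As deposited, the myelin list shifted lower (median -0.22, camera adjusted p = 0.0132), not with an estimated correlation (adjusted p = 0.539). It lost its call without knockout replicate 2 (median -0.11, adjusted p = 0.143) and without control replicate 1 (median -0.15, adjusted p = 0.0870), and the neuron median was -0.16 without knockout replicate 4.

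Most hair cell genes did not pass. Of 29 members of the hair cell list, Calb2 fell over all features, and Calb2 and Pcp4 fell when adjusted over the list alone. The motor protein gene Myo6 was at -0.53, Myo7a at 0.04, Pou4f3 at -0.10 and Otof at -0.03. The list level was 5.39 ± 0.05 in knockout and 5.56 ± 0.06 in control animals (SD, n = 4; exact permutation p = 0.0286, the smallest possible; adjusted p = 0.248 over lists), while the list median was -0.03 and the camera adjusted p 0.0688, and 0.252 without Calb2 (level difference -0.12, exact permutation p = 0.0286). After cyclic loess the list passed (median -0.11, camera adjusted p = 0.00428, and 0.219 with an estimated correlation), and it passed in 9 of 28 alternatives, among them those without knockout replicate 4 (adjusted p = 0.0220) and without control replicate 4 (adjusted p = 0.0263). Genes that skeletal muscle also expresses were among its lower members, with Pvalb at -0.96, Xirp2 at -0.48 and Smpx at -0.36, beside a muscle list level difference of -0.79. Without 5 such members the hair cell level was 5.37 ± 0.05 in knockout and 5.49 ± 0.04 in control animals (SD, n = 4; exact permutation p = 0.0286; camera adjusted p = 0.260). Calb2, Pcp4 and Myo6, picked as the lowest after the values were seen, were then left out too. The other 21 members were at 5.20 ± 0.05 in knockout and 5.19 ± 0.05 in control animals (SD, n = 4, exact permutation p = 0.743). After cyclic loess these 21 differed by -0.04 (exact permutation p = 0.114). Leaving out the lowest members shrinks a fall by construction, so these values do not show that the other members were unchanged. The inner hair cell list, with 9 members, differed at the same exact permutation p of 0.0286 (camera adjusted p = 0.0578, 0.494 without Calb2 at an exact permutation p of 0.200, 0.0206 without knockout replicate 1 and 0.0181 without control replicate 2). The hair bundle and mechanotransduction list of 34 members had a median of 0.05 (adjusted p = 0.445). Its members included Ptprq at -0.45, Rdx at -0.35, Ush1g at 0.25 and Gipc3 at 0.29. In the outer hair cell list (adjusted p = 0.494), the prestin gene Slc26a5 was at 0.02, Ocm at -0.14, Lbh at -0.30, Sri at -0.22, Pde6d at -0.25 and Tmprss7 at 0.21. Genes reported lower in a Mir96 seed mutant, namely Slc26a5, Ocm, Gfi1 (0.06) and Ptprq, did not pass as a list (adjusted p = 0.494). Reported microRNA targets, 28 measured, had a median of -0.08 (camera adjusted p = 0.0432, and 0.539 with an estimated correlation), with Adcy6 at -0.33, Btrc at -0.38, Idh2 at -0.33 and Slc1a1 at 0.44, and 0 of them passed. After cyclic loess the median was -0.01 and the mean -0.0011 (adjusted p = 0.812), and the deposited median lay at percentile 68.2 of random lists matched on mean level, so the shift was no larger than that of other genes of that level. The target list lost its call without knockout replicate 3 or 4 or control replicate 1 or 2 (adjusted p = 0.0852 to 0.113), and its median was -0.13 without knockout replicate 2 and -0.15 without control replicate 3.

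Other cochlear cell types had lists that shifted lower without a called member. The supporting cell list had a median of -0.13 (camera adjusted p = 0.0342), with Fbxo2 at -0.42, the connexin gene Gjb6 at -0.35, Otogl at -0.31 and Slc1a3 at -0.29. The stria vascularis list had a median of -0.13 (adjusted p = 0.0432), with Slc12a2 at -0.41, Esrrb at -0.33, Lrp2 at -0.30 and Kcne1 at -0.28. The fibrocyte and otic mesenchyme list had a median of -0.14 (adjusted p = 0.0375), with Slc4a11 at -0.57, Coch at -0.35, Otos at -0.24 and Lum at -0.24. The bone and cartilage list had a median of -0.21 (adjusted p = 0.00268), with the collagen genes Col1a1 at -0.42 and Col1a2 at -0.33, Acan at -0.33 and Ibsp at -0.24. A second feature of Col1a2 read -0.05. With an estimated correlation the adjusted p was 0.539 for supporting cells, 0.587 for stria and fibrocytes and 0.579 for bone. After cyclic loess all 4 lists lost their call, with medians of -0.0039 for supporting cells (adjusted p = 0.316), -0.09 for stria (0.155), -0.04 for fibrocytes (0.625) and -0.05 for bone (0.293). Among random lists matched on mean level the deposited medians lay at percentile 3.98 for supporting cells, 6.99 for stria, 59.3 for fibrocytes and 18.2 for bone. The supporting cell list lost its call without knockout replicate 2 or 3 or control replicate 1 (adjusted p = 0.0870 to 0.179), the stria list without knockout replicate 2 or 3 or control replicate 1 or 3 (0.0819 to 0.387) and the fibrocyte list without knockout replicate 2 or 3 or control replicate 1 or 2 (0.0707 to 0.349). The fibrocyte median was -0.22 without knockout replicate 1 and -0.08 without knockout replicate 3, and the bone median -0.32 without knockout replicate 1 and -0.12 without knockout replicate 3 or control replicate 2. The melanocyte list (adjusted p = 0.883; Dct -0.27, Pmel 0.21, Gpr143 0.15, Mlana -0.16) and the osteoclast list (adjusted p = 0.0688; Oscar -0.34, Atp6v0d2 -0.34, Acp5 -0.19, Ctsk -0.19) did not pass, though the osteoclast list did without knockout replicate 1 (0.0134) or control replicate 3 (0.0303).

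The cell cycle, B cell and erythroid lists shifted lower, and the neutrophil and macrophage lists did not pass. All 18 cell cycle genes had negative differences, with a median of -0.30 (camera adjusted p = 1.6e-05), as in Cenpe at -0.41, Mcm5 at -0.32, Aurkb at -0.31 and Ccna2 at -0.29, and 0 passed. The list level, 7.41 in knockout and 7.68 in control animals, lay in the highest decile of features by mean level. Only 12.3% of all features of that decile were higher in knockout cochlea. In the B cell list, 5 of 13 members fell when adjusted over the list alone: the receptor genes Cd79b (-0.44) and Cd79a (-0.39), and Pax5 (-0.52), Igll1 (-0.30) and Blnk (-0.43). After cyclic loess these 5 members read -0.23 for Cd79b, -0.24 for Cd79a, -0.38 for Pax5, -0.10 for Igll1 and -0.22 for Blnk. All but Pax5 then missed the 0.05 threshold even before adjustment, and the adjustment over the list alone was not repeated. The deposited B cell median was -0.30 (adjusted p = 0.000318). The erythroid median was -0.25 over 6 members (adjusted p = 0.0342), with Slc4a1 at -0.41, Rhag at -0.45, Rhd at -0.27 and Klf1 at -0.23. With an estimated correlation the adjusted p was 0.539 for cell cycle and B cell and 0.579 for erythroid genes. The list levels per animal gave an exact permutation p of 0.143 for cell cycle, 0.0571 for B cell and 0.257 for erythroid genes. With signal range as a covariate the medians of the cell cycle list (0.12) and the erythroid list (0.20) turned positive. The erythroid list lost its call without knockout replicate 1 or 4 or control replicate 1 or 4 (adjusted p = 0.0707 to 0.202), and its median was -0.41 without control replicate 3 and -0.12 without control replicate 4. The neutrophil list did not pass (adjusted p = 0.657), with S100a9 at 0.35, S100a8 at 0.27, Retnlg at 0.22 and Prtn3 at -0.39, though it passed as higher without control replicate 4 (median 0.12, adjusted p = 0.00626). For macrophages the list median was -0.05 and the mean 0.0011 (adjusted p = 0.940), with Cx3cr1 at 0.34, Cd163 at 0.22, Csf1r at -0.20 and Cd68 at -0.22.

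Skeletal muscle genes differed most between animals. The list median was -0.74 (camera adjusted p = 1.6e-05, and 0.539 with an estimated correlation), with the myosin gene Myh4 at -1.67, Mylpf at -1.30, Pvalb at -0.96 and Actn3 at -0.90, and 0 of 15 members passed. Without control replicate 2 the median was -0.30 (adjusted p = 0.00167). The level ranged from 5.53 to 6.71 in knockout (SD 0.52) and from 6.47 to 8.30 in control animals (SD 0.85). The groups overlapped, with a difference of -0.79 (exact permutation p = 0.171). Lists that did not pass were brain (adjusted p = 0.917; Ttr -0.27, Gabra6 0.27, Gad2 0.17, Cnp -0.17), interferon response (0.940; Isg15 -0.36, Ifit3 0.31, Oasl2 0.10, Ifit1 -0.10), immediate-early and stress (0.175; Btg2 -0.34, Dnajb1 -0.25, Hspa8 -0.24, Nr4a1 -0.17), sex-linked (0.820; Eif2s3y 0.28, Xist -0.26, Uty 0.07, Kdm5d 0.05), targeted cluster (0.0688) and locus neighbours (0.684; Ahcyl2 -0.34, Mest -0.24, Klhdc10 -0.27, Cep41 0.22). The other 3 features of Hspa8 read -0.21 to -0.16. The stress list passed without control replicate 3 (0.0382), and the targeted cluster without knockout replicate 1 or 4 or control replicate 2 or 4 (0.0181 to 0.0489). In all, 11 of 26 lists passed with the preset correlation, all 11 lower, 0 passed with the estimated correlation and 0 with fry. With signal range as a covariate 10 passed, 6 lower and 4 higher, the higher ones being the cell cycle, erythroid, neutrophil and macrophage lists. Signal range was itself lower in knockout arrays (1.40 ± 0.03 against 1.49 ± 0.06, SD, n = 4) and is computed from the tested features. That covariate therefore overlaps with genotype, and values adjusted for it do not show that a list was higher. Fewer passed without control replicate 1 (5 lists) and without knockout replicate 2 or 3 (7 lists each). Xist ranged from 8.84 to 9.66 and the mean of the Y-linked genes from 2.48 to 2.84 over the 8 arrays. By mean level over the arrays Xist lay at the 99.1th percentile of features, and Eif2s3y, Kdm5d and Uty at percentiles 2.8, 5.3 and 5.6. No array therefore read as male, and the Y-linked covariate, built from dim features, does not measure a difference in sex.

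**Figure D2:**
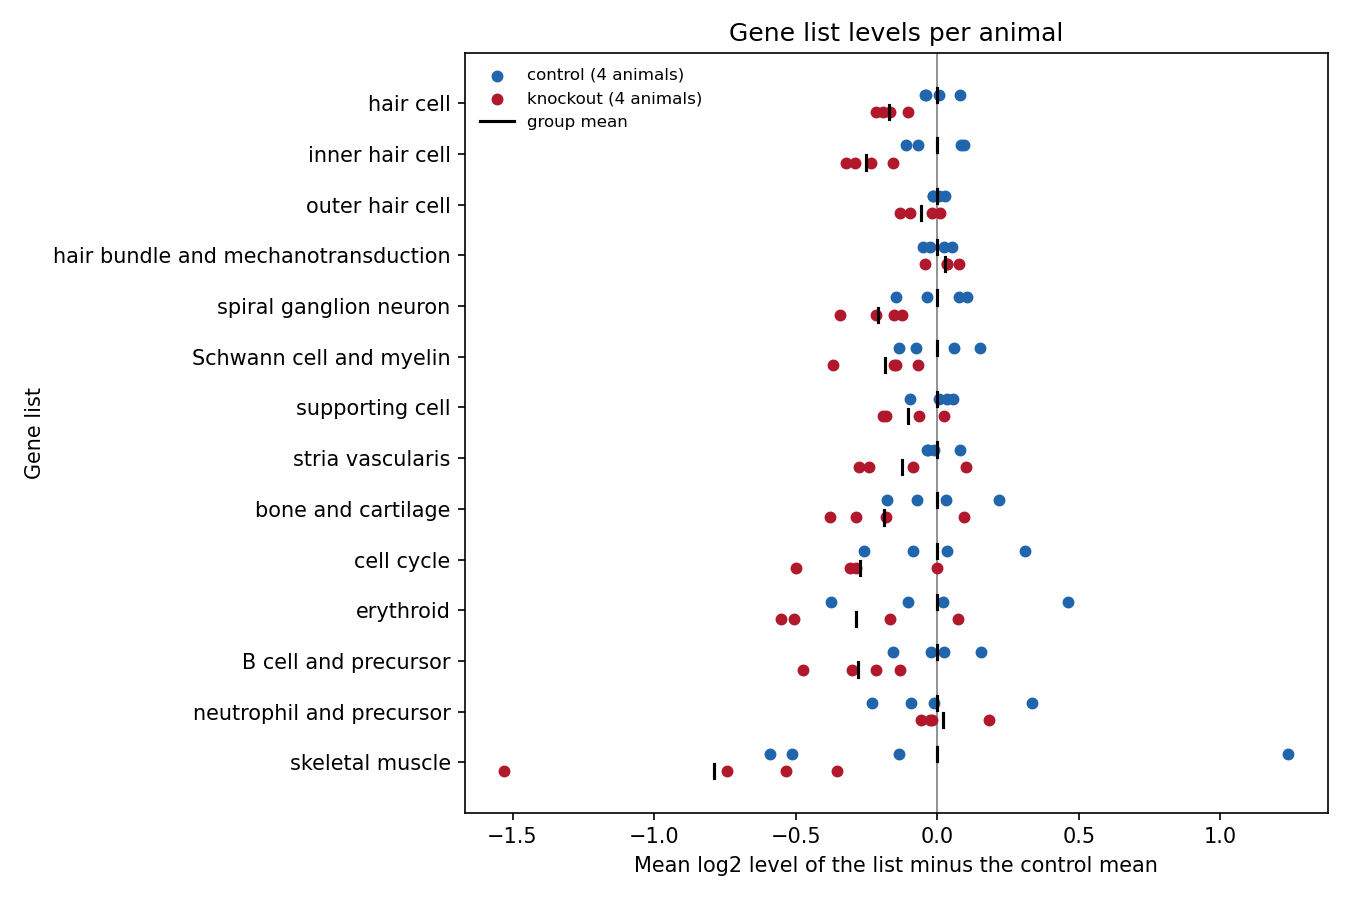
Mean log2 level of each gene list (vertical axis) in every animal minus the control mean of that list (horizontal axis, log2), with blue points the 4 control animals, red points the 4 knockout animals and black bars group means. The hair cell levels of knockout animals all lie below those of control animals, and the skeletal muscle levels spread most within each group.

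The differences followed the mean level of the features. Among the 10 deciles of features by mean level, the median log2 difference went from 0.13 in the lowest to -0.21 in the highest, and after cyclic loess from 0.0034 to -0.01. The SD of log2 values per array was 1.40 ± 0.03 in knockout and 1.49 ± 0.06 in control animals (SD, n = 4; exact permutation p = 0.0571), and control replicate 3 (1.41) lay within the knockout range of 1.37 to 1.44. After cyclic loess 6 lists passed, 5 lower and 1 higher, and 3 of the 11 lists were among them: spiral ganglion neuron, B cell and skeletal muscle. The others were the hair cell and targeted cluster lists, lower, and the neutrophil list, higher. With an estimated correlation 0 passed after cyclic loess (smallest adjusted p = 0.219; skeletal muscle 0.628, targeted cluster 0.285).

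**Figure D3:**
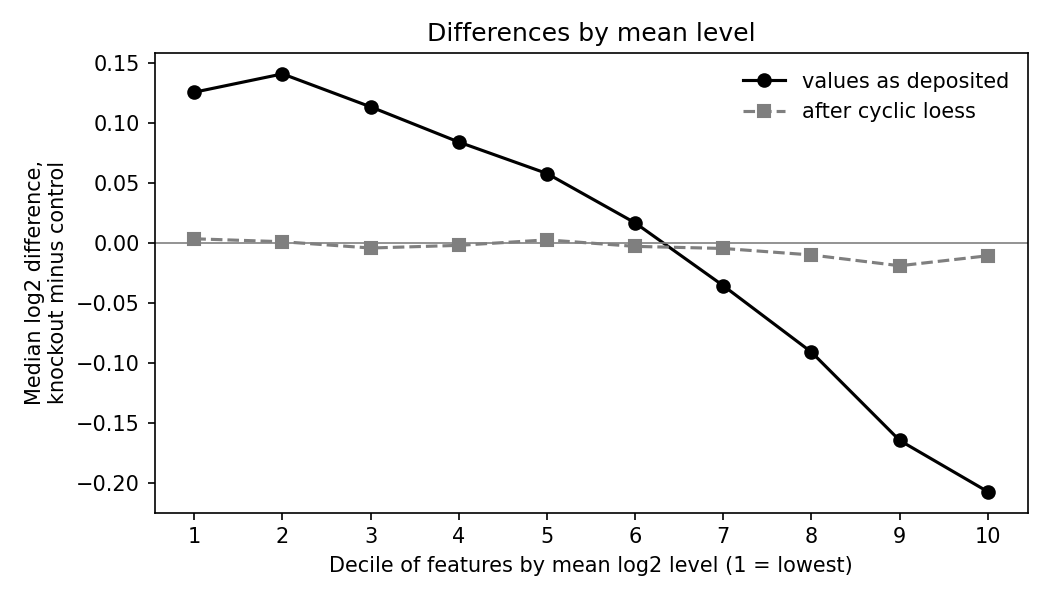
Median log2 difference, knockout minus control (vertical axis), for each decile of the tested features by mean log2 level (horizontal axis), with black circles the values as deposited and grey squares the values after cyclic loess. The deposited medians run from 0.13 in the lowest decile to -0.21 in the highest decile.

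Genes near the targeted locus were compared with the rest, since a targeted allele can carry flanking sequence of another strain. Of the 100 features with the smallest p, 98 had a position, and 2 of these, Mir96 and Clec2l, lay within 10 Mb of the locus, against 140 of 23217 other features (Fisher's exact test, odds ratio 3.43, p = 0.120). Mir96 is itself a targeted gene and says nothing on flanking sequence. Without the 3 microRNA genes of the cluster, 1 of 98 such features, Clec2l, lay within 10 Mb, against 138 of 23214 others (Fisher's exact test, odds ratio 1.72, p = 0.444).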

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

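An animal far from the other 3 of its group was found in 14 of 280 groups of 4 values examined (by Dixon's ratio at its 95% critical value), and chance alone gives about 14. In knockout replicate 1, Mir96 was low at 4.01, Retnlg low at 9.37 and Klhdc10 high at 6.21. In knockout replicate 2, Nefl was low at 6.01 and the neutrophil list level high at 8.78, in knockout replicate 3 Mir183 was low at 1.82, and in knockout replicate 4 Zfp600 was high at 6.87 and Isg15 low at 4.51. Among control animals, Cep41 was high at 5.20 in replicate 1, Vsnl1 high at 8.19 in replicate 2, Otos low at 10.6 in replicate 4, and in replicate 3 Mal was low at 6.52, Adcy6 low at 6.29 and Ifit3 high at 6.57. No explanation of these values was tested.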

How the results depend on the processing

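Cyclic loess, the signal range covariate, the removal of both muscle extremes the lists without Calb2, muscle-expressed or lowest members, and the locus comparison without the targeted genes were chosen after seeing the data. Calls numbered 1 over all features of the table, 8 with array weights, 1 with the muscle covariate, 1 with the signal range covariate, 7 at an adjusted p under 0.1, and 1 to 21 when 1 array was left out, the 21 without control replicate 3. Features at a nominal 1.5-fold difference numbered 1045 over all features (739 higher), 98 at a mean of at least 5 (53 higher), 84 in the upper part by mean (43 higher), 130 with the blood and marrow covariate, and 156 to 488 with 1 array left out. Fewer features were tested for the counts of 98 and 84, and those that dropped out were mostly higher ones. Higher features went from 155 in the main test to 53 and 43, and lower ones from 52 to 45 and 41. Lists past the threshold numbered 5 at a mean of at least 5, 5 in the upper part, 7 after quantile normalization, 6 with the Y-linked covariate, 6 after cyclic loess, 0 with estimated correlation, 0 with fry, and 5 to 13 with 1 array left out. Lists at an exact permutation p of at most 0.05 numbered 3, and 5 in the upper part, 5 after quantile normalization, 5 after cyclic loess, 0 without both muscle extremes, where 3 against 3 animals cannot reach it, and 1 to 5 with 1 array left out. Mir96 lost its call over all features (-1.48, adjusted p = 0.184) and with the muscle covariate (-1.57, adjusted p = 0.0568), and ran from -1.62 to -1.30 with 1 array left out; its adjusted p ran from 0.00164 to 0.184 over alternatives. The filters at a mean of 5 and in the upper part removed Mir96, which has no value there.

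The skeletal muscle median was -0.021 with the muscle covariate, which is built from those genes. With signal range as a covariate the erythroid median was 0.20, the cell cycle median 0.12 and that of reported microRNA targets 0.0074. Except for the counts set by fewer animals and the muscle value, the cause was not tested. With the replicate number as a block 3 features were called (Calb2, Mir96 and Olfr99) and 11 lists passed; same-numbered animals deviated together at correlations of 0.06, 0.21, 0.21 and -0.29, and number 3 alone correlated best with its own number, so the numbers were not taken to pair animals. The odds ratio near the locus was 3.14 within 5 Mb and 1.59 within 20 Mb, and without the targeted genes 1.72 within 10 Mb, 0 within 5 Mb and 0.793 within 20 Mb, since Mir96 was 1 of the 2 hits. Grouping by seed matches, with its alternatives, was not run. Signal over background was not analysed here, which limits statements on dim features such as Mir183.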

Other observations

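Olfactory and vomeronasal receptor genes, examined after the values were seen, read mostly higher in knockout arrays, as did other dim features. Of 1405 such features 1183 (84.2%) had positive differences, against 75.2% of other features when spread alike over the deciles of mean level. Their median level was 3.21, their median difference 0.19, and 0.08 after cyclic loess, and 0 were called. Their mean level per animal did not separate the groups (exact permutation p = 0.0857), and enrichment was not tested. The neutrophil list, which did not pass on the deposited values, shifted higher after cyclic loess (median 0.17, camera adjusted p = 0.000187, and 0.487 with an estimated correlation).

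Of the tests that follow, those of signal range against genotype, of the shift with mean level and of bone marrow were chosen after the results were seen; the others were chosen before. The bounds for the signal range test were set without a sign, and that test was then found to be largely fixed by construction. For neuron genes the bound first set required an exact permutation p of at most 0.05 after cyclic loess and was not met, but that p was 0.0571 before and after, so it could not bear on the trend; a list that stayed past its threshold by more than 2 SE was read instead, a criterion set with the values known. The difference in list level kept after cyclic loess was 101% for neurons, 35.4% for cell cycle, 31.7% for erythroid and 56.2% for B cell genes.

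Features of low mean level read higher and those of high mean level lower in knockout arrays. Across features, the slope on signal range estimated within the groups correlated with the log2 difference at a Spearman's rho of -0.60. The signal range is the SD of an array's values, so these slopes order features by mean level largely by construction (rho 0.47 with mean level), and the test decides nothing on a difference in signal range between arrays as a cause. Whether the range goes with the genotype cannot be told apart with 4 animals per group (exact permutation p = 0.0571).

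Neuron genes were lower in knockout cochlea. Cyclic loess removed the trend with mean level and left the list median at -0.12, against -0.10 as deposited, and the list level difference at -0.21 (SE 0.07; camera adjusted p = 0.000187, and 0.487 with an estimated correlation), which argues against the shift with mean level as the whole cause. A smaller share of neural tissue stays open. The SD of the differences of 22 neuron genes with a mean of at least 5 was 0.38, as large in 1 of the 35 splits, the real 1 (highest other 0.28), but the mean fall was also as large in 1 split alone, and a fall raises the SD where genes differ in how much of their signal is neural, so this test decides nothing. The myelin list was lower too, with 11 of 13 members negative, but did not pass after cyclic loess (median -0.10, camera adjusted p = 0.0882, exact permutation p = 0.343). Among random lists matched on mean level the deposited medians lay at percentile 1.23 for neurons and 0.88 for myelin. Such percentiles ignore the spread between animals, as skeletal muscle lay at percentile 0 with an exact permutation p of 0.171. An effect of genotype within neurons may equally account for Snap25, Calb1 and Nefl.

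Cell cycle, B cell and erythroid genes were lower together, with a joint median of -0.29 as deposited and -0.10 after cyclic loess, so the shift with mean level may account for most of it. Among 10000 random lists matched on mean level the medians lay at percentile 22.8 for erythroid, 0.22 for cell cycle and 0.12 for B cell genes. After cyclic loess the B cell list stayed past its threshold (level difference -0.16, SE 0.08; camera adjusted p = 0.0225, and 0.487 with an estimated correlation), narrowly against the trend as its whole cause, while the cell cycle list (adjusted p = 0.0617) and the erythroid list did not. A smaller share of bone marrow as a whole was taken to lower neutrophil genes as much. The neutrophil minus B cell level was 1.85 ± 0.09 in knockout and 1.55 ± 0.12 in control animals (SD, n = 4, exact permutation p = 0.0286, the smallest possible), so the neutrophil and B cell lists did not fall alike. Neutrophil list members went both ways, 9 higher and 7 lower, and 0 passed. They ran from Prtn3 at -0.39, Elane at -0.27 and Mpo at -0.23 to the abundant Ngp at -0.01, S100a8 at 0.27 and S100a9 at 0.35. A level over members that move apart cannot decide on the share of marrow, which stays open. Fewer cells of the B lineage, or an effect of genotype on them, stay open too.

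Chance was not excluded for the counts of the comparison. Of the 35 splits of the 8 arrays, 2 gave at least 3 called features (highest other 1055), 2 gave at least 207 features at a nominal 1.5-fold difference (highest other 345) and 3 gave at least 11 lists (highest other 13). The split with 1055 calls set knockout replicates 1, 3 and 4 with control replicate 3, the 4 arrays of smallest signal range, against the rest. It differs from the genotype split only in the exchange of knockout replicate 2 and control replicate 3. Mir96 read 4.26 in knockout replicate 2 and 6.23 in control replicate 3, so these labels were not exchanged. Genotype alone, whose split gave 3 calls, thus does not account for the 1055. The split followed the first principal component, the main axis of variation between arrays (40.7% of variance). It was negative in knockout replicates 1, 3 and 4 and control replicate 3, and positive in the rest. What this axis reflects, and how far it goes with genotype, cannot be told apart with 4 animals per group.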
